A study of Mus musculus with 6 samples.

How the data were processed

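Whole fetal livers were dissected from mouse embryos at embryonic day 11.5, and their total RNA was hybridised to Affymetrix arrays, per the labels. In the cross described by the labels' protocols, the Stab2-Cre transgene drives recombination of floxed alleles of Gata4. Stab2 is a scavenger receptor gene of sinusoidal endothelium, and Gata4 encodes a zinc-finger transcription factor. The 6 arrays fall into 2 groups of 3: livers labelled knockout, and control livers whose titles name them heterozygous. The labels call the replicates biological. How many embryos went into an array, and which embryos were littermates, is not given in the sources used here.

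The deposited values are log2 expression values made by the authors with RMA, per the submitters' processing notes, which give no version. RMA subtracts background, quantile-normalises the arrays and summarises the probes of each feature. The chip type, the chip definition and further settings are not given in the sources used here. The log2 scale was read from the deposited values, which run from 2.55 to 13.9 in each array with a median of 5.43. Sorted values were identical in all 6 arrays, which is what quantile normalisation leaves. Every array therefore has the same distribution, and a change in total RNA per liver or a shift of most genes cannot be seen. A value measures a transcript's share of the RNA of a mixed tissue. A change in cell composition and a change of expression within a cell type give the same kind of difference. No value of signal over background was used, so a dim feature could not be told from background, and for arrays only their number limits the precision that can be stated.

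Of 24479 features, 23281 were named through the platform's annotation, 23156 of them with the current symbol from a RefSeq gene table of GRCm38.p6 and 125 with the annotation's own symbol. No feature had several genes, and 1198 had no name here. A pair of features shared a gene name in 2 cases and the feature with the higher mean over the 6 arrays was kept, which left 23279 genes. The build of the arrays' annotation is not given in the sources used here, so the gene table served only for names, for membership of the X and Y chromosomes and for the order of neighbouring genes. Columns of values without a sample numbered 0.

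Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with no trend and not robust) on the 6 arrays, as labelled knockout minus control with no covariate. Benjamini-Hochberg adjustment covered the 23279 genes, and the threshold was an adjusted p of 0.05. The fit had 4 residual degrees of freedom, to which the moderated variance added 4.06. Standard errors are those of the moderated fit, and group values are means ± SD over n = 3 arrays. A rank-based exact permutation test of 3 arrays against 3 cannot give a two-sided p below 0.1, so single genes rest on the model fitted across all genes. No filter on dim features was applied.

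Before the data were examined, 30 gene lists with 578 members were written down. They cover GATA factors, endothelial, mesenchymal, hepatic and blood cell types, matrix, signalling, stress, cell cycle and neighbouring tissues, and 544 members matched a tested gene, 5 of them through an older symbol. The remaining members were not analysed here. The 27 lists other than GATA factors, embryonic globins and sex-linked genes were tested with camera on the moderated t-statistics, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 27 lists. Camera with the correlation estimated from the data and fry, a rotation test of whether a list's genes move on balance one way, were run beside it. For each list, members past the gene test are also counted after adjustment over the list alone. Lists overlap in a few members, such as Thbs1, which is in the interstitial matrix and megakaryocyte lists. The per-array value of a list is the median over its members of the log2 value minus the control mean.

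Genes named in the text follow a rule also fixed then: the GATA family; the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap; up to 4 members of each list with the smallest p; and 14 preset markers. The markers were Stab2, Lyve1, Pecam1, Cdh5, Alb, Afp, Kit, Klf1, Hbb-bh1, Col1a1, Pdgfb, Myc, Wnt2 and Kitl. Predicted genes, Riken clones, expressed sequence tags, olfactory and vomeronasal receptors, histone genes and small RNA genes were passed over among the largest changes, which affected 1 rise and 3 falls. Genes outside the rule are said to be so where they appear.

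Alternatives fixed beforehand were limma with a variance trend, robust eBayes, a new quantile normalisation, median centring, leaving out the dimmest 25% or 50% of genes, averaging features or testing each alone, array weights, the replicate number as a block, leaving out genes on X and Y, an adjusted p of 0.1, a fold change of at least 1.5, the other list tests, and leaving out each array in turn. A sex term, separating arrays with Y-linked signal from the rest, was added after the data were seen. The statistics were tested on simulated data for this comparison: of 200 changed genes among 23279, 36% were recovered at a log2 change of 0.5, 98% at 1 and 100% at 1.5 and at 2. Of 182 calls, 15 (8.24%) were false, and camera called 10 of 10 shifted lists and 0 of 10 unshifted ones. Each gene was simulated independently, so this does not test camera on lists whose members vary together. In the data the estimated correlation between members reached 0.70, in the megakaryocyte list. Figures were drawn with matplotlib 3.10.9.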

Results

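Expression was measured in whole fetal livers at embryonic day 11.5 on 6 arrays, 3 of livers labelled as carrying the Stab2-Cre-driven Gata4 knockout and 3 of control livers. The series title frames the question as what endothelial GATA4 does for the identity of liver vessels, for growth of the liver and for blood formation in the embryo. The number of arrays limits the precision of each value, and all 6 arrays have the same median (5.43) because the deposited values were quantile-normalised.

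Gata4 itself was higher, not lower, in the livers labelled knockout. Its feature read 9.91 ± 0.05 in control livers and 10.42 ± 0.19 in livers labelled knockout (log2 value, mean ± SD, n = 3), a 1.43-fold rise (log2 fold change 0.51, SE 0.12, limma adjusted p = 0.0409). Whole liver holds other cells that express Gata4, such as mesenchyme, and the feature's probes may lie outside the deleted part, so this value does not check the labels, and every direction given here rests on them. Of the other GATA factors, Gata5 rose by 0.89 (SE 0.19, adjusted p = 0.0339) and Gata6 by 0.73 (SE 0.15, adjusted p = 0.0326) on the log2 scale. The erythroid and megakaryocytic factor Gata1 (−0.63, adjusted p = 0.0537), the progenitor factor Gata2 (−0.34, adjusted p = 0.138) and Gata3 (0.26, adjusted p = 0.362) did not pass. Adjusted over the 6 measured GATA genes alone, 3 were higher and 2 lower, Gata1 and Gata2. The Gata4 call was lost without any 1 of 5 arrays, with an adjusted p of 0.0645 without labelled knockout replicate 1, 0.101 without labelled knockout replicate 3, and 0.105, 0.101 and 0.144 without control replicates 1, 2 and 3. With a sex term it was lost too (0.46, adjusted p = 0.310). The Gata5 and Gata6 calls each held in 1 of the 6 fits without 1 array, with adjusted p-values up to 0.109 and 0.122.

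Livers labelled knockout had lower expression of blood cell genes and higher expression of hypoxia-response, matrix and mesenchymal genes. This rests on counts of single genes, on camera with a preset correlation and on fry. Fry gave these lists adjusted p-values from 0.0110 to 0.0544, the highest being that of megakaryocyte genes, which did not pass. With an estimated correlation camera passed none of them, at adjusted p-values between 0.166 and 0.226. Of 23279 genes tested, 836 were higher and 644 lower, and 97 and 109 of these differed at least 2-fold. The largest rise was that of Slc7a3, a cationic amino acid transporter, at 7.91-fold (log2 fold change 2.98, SE 0.26, adjusted p = 0.00591). Sparcl1, a matricellular protein related to Sparc, rose 6.21-fold (2.64, SE 0.12, adjusted p = 0.000296), and Prnd, a prion-like protein, 5.31-fold (2.41, SE 0.23, adjusted p = 0.0074). The mTORC1 inhibitor Ddit4 (1.80), the circadian repressor Ciart (1.69), the pericyte gene Rgs5 (1.69), the lipoprotein receptor gene Vldlr (1.59), the secreted factors Igfbp1 (1.52) and Stc2 (1.47), and the transcriptional repressor Bhlhe40 (1.48) completed the 10 largest rises under the naming rule. The rule passed over 1 rise and 3 falls. One of them, the Riken clone D030028A08Rik, changed by −2.54 (adjusted p = 0.00525), further than any of the falls named next. Under the rule, the 10 largest falls were led by Adgre4, an adhesion receptor of myeloid cells, which was 4.29-fold lower (−2.10, SE 0.29, adjusted p = 0.0128). The others were the myeloid lectin Clec4a1 (−1.85), the macrophage transcription factor Spic (−1.80), the mast cell protease Cpa3 (−1.76), Ms4a3 of granulocyte and monocyte progenitors (−1.72), Igsf6 (−1.68), the phagosomal metal transporter Slc11a1 (−1.66), the eosinophil granule protein Prg2 (−1.58), haptoglobin Hp (−1.57) and Mpeg1, a pore-forming protein of macrophages (−1.56).

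**Figure D1:**
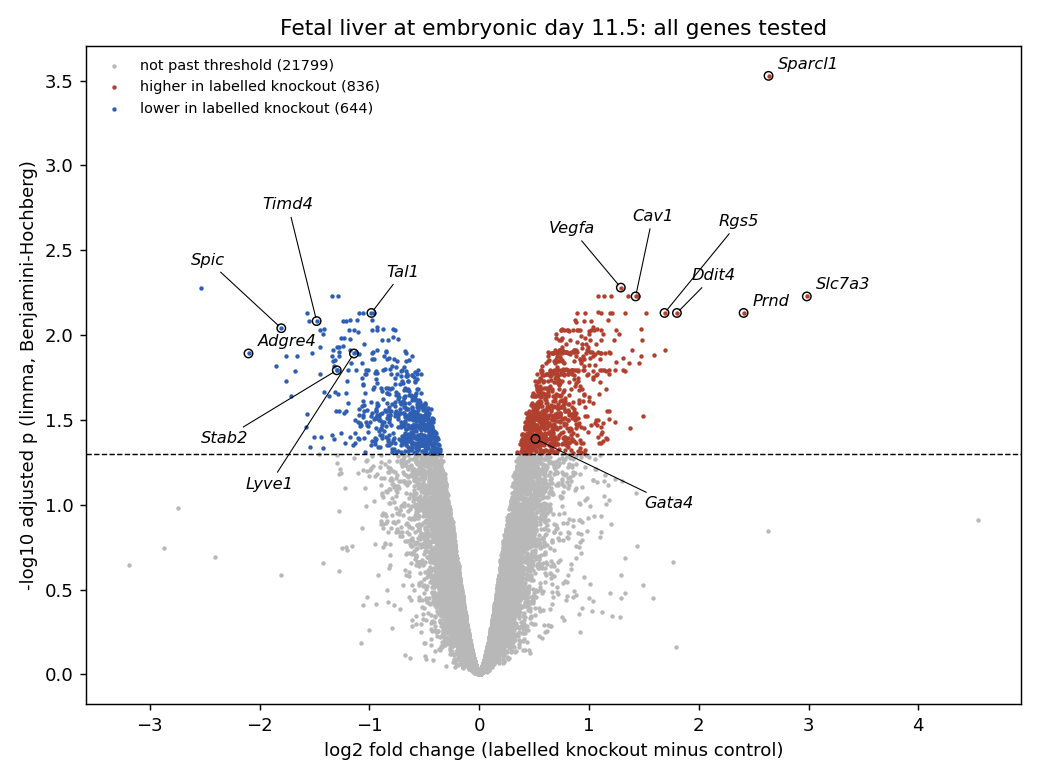
Log2 fold change (labelled knockout minus control, x axis) of each of 23279 genes against −log10 of its limma adjusted p (y axis), from 3 arrays per group; the dashed line marks an adjusted p of 0.05. Red points are the 836 genes that were higher and blue points the 644 that were lower in livers labelled knockout, with Sparcl1 at the top (log2 fold change 2.64) and Gata4 just above the line (0.51).

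In all 1480 genes past the threshold the values of the groups did not overlap, as was so for 27.3% of all genes, against 10% by chance. The count fell when any 1 array was left out: 1395 genes passed without labelled knockout replicate 1, 922 without replicate 2 and 262 without replicate 3, and 555, 367 and 41 without control replicates 1, 2 and 3. Over the 1480 genes the median absolute log2 fold change was 0.62 to 0.69 in these fits, against 0.66 in the main one. Their median standard error was 0.121 to 0.136, against 0.121. Each such fit has fewer arrays, so a lost call need not mean a smaller difference. Of 87 genes named here that passed, 13 did so in every one of these fits: Slc7a3, Sparcl1, Prnd, Ddit4, Rgs5, Igfbp1, Vegfa, Cav1, Gpr182, Mrc1, Marco, Mpeg1 and Tal1. In none of them did Ccng1, E2f1, Krt19 and Vim pass. Embryo sex was not balanced. Xist read between 10.2 and 10.7 in the livers labelled knockout and in control replicate 2 and 3.58 and 3.96 in control replicates 1 and 3, and Y-linked Uty read 8.18 and 8.15 in those 2 controls and at most 4.08 in the other arrays. With a sex term 3 genes passed (Sparcl1, Prnd and Rgs5), and for each tested gene list below the median against control replicate 2 alone is given beside the main one.

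Markers of sinusoidal endothelium, the fenestrated lining of liver capillaries, were lower. Of 22 measured, 10 fell, 1 rose and 11 did not pass (10 and 2 adjusted over the list alone), with a median log2 fold change of −0.30 and −0.24 against control replicate 2 alone. The median was −0.18 with the dimmest 25% of genes left out and −0.66 with the dimmest 50% left out. Stab2, whose promoter drives the Cre, fell 2.46-fold (−1.30, SE 0.20, adjusted p = 0.0161). The hyaluronan receptor Lyve1 fell 2.20-fold (−1.14, SE 0.16, adjusted p = 0.0128), the orphan receptor Gpr182 2.26-fold (−1.18, SE 0.12, adjusted p = 0.00813), the mannose receptor Mrc1 2.08-fold (−1.06, SE 0.10, adjusted p = 0.0074) and the transcription factor Tfec 2.94-fold (−1.55, SE 0.17, adjusted p = 0.00821). Mrc1 and Tfec are also expressed by macrophages, whose own markers were lower too. The member that rose was Rspo3, a potentiator of Wnt signalling (0.77, SE 0.12, adjusted p = 0.0161), and Wnt2 did not pass (0.19, adjusted p = 0.713). Camera gave the list an adjusted p of 3.12e-07 with the preset correlation and an adjusted p of 0.166 with an estimated correlation. By fry it was 0.0148. The Stab2 call was lost without control replicate 2 (adjusted p = 0.0554) or control replicate 3 (0.0678), and the Lyve1 call without control replicate 3 (0.0632).

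Genes of continuous capillaries, vessels without fenestrae, were on balance higher. Of 24 measured, 6 rose, 2 fell and 16 did not pass (11 and 2 adjusted over the list alone; median 0.34, and 0.39 against control replicate 2 alone). Cav1, the structural protein of caveolae, rose 2.69-fold (1.43, SE 0.12, adjusted p = 0.00591), the tip cell gene Esm1 1.82-fold (0.86, SE 0.11, adjusted p = 0.0122) and the sialomucin Emcn by 1.00 on the log2 scale (SE 0.15, adjusted p = 0.0151), whereas the cell cycle regulator Rgcc fell by 1.31 (SE 0.19, adjusted p = 0.0141). Of 18 markers shared by all endothelium, 5 rose, 0 fell and 13 did not pass (8 higher adjusted over the list alone; median 0.30, and 0.36 against control replicate 2 alone). The adhesion molecule Pecam1 rose by 0.63 (SE 0.09, adjusted p = 0.0141), the VEGF receptor Flt1 by 0.65, the cadherin Cdh5 by 0.53 and the transcription factor Ets1 by 0.49. Adjusted p-values of the continuous and the shared list were 1.01e-05 and 3.30e-05 by camera, and adjusted p = 0.166 and 0.285 with an estimated correlation. Fry gave 0.0110 and 0.0808. The medians of both lists were similar (0.34 and 0.30), and that of hepatoblast genes was 0.35, so a rise particular to continuous capillaries was not shown.

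**Figure D2:**
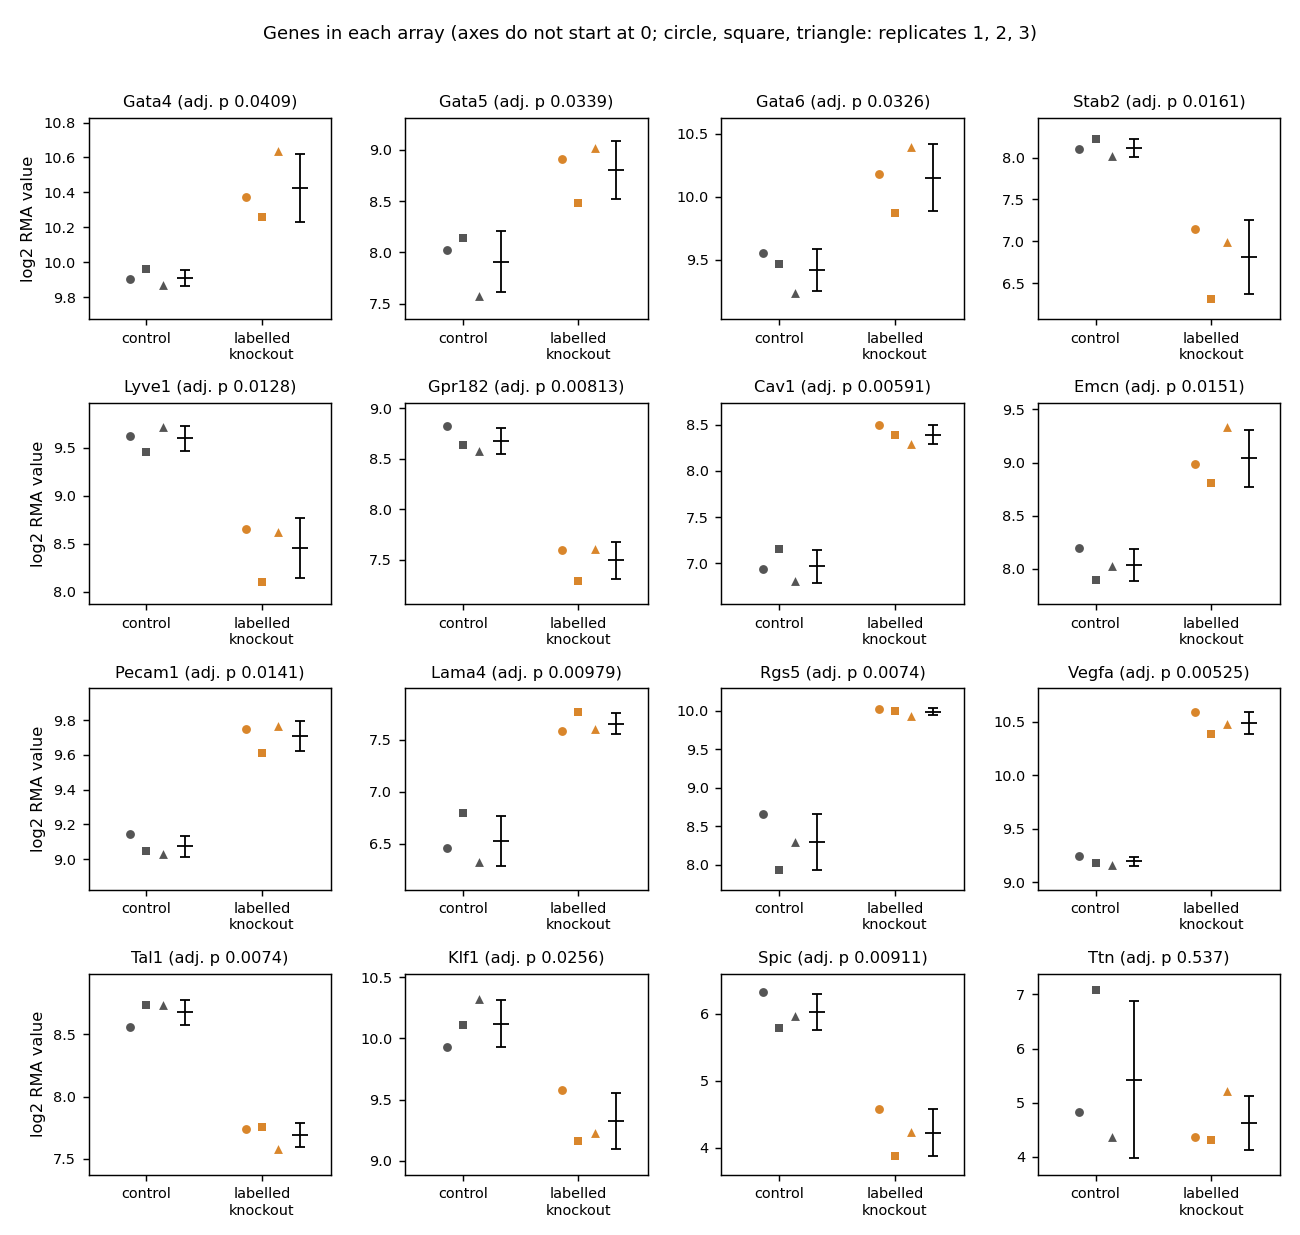
Log2 RMA values (y axes, which do not start at 0) of 16 genes in each control array (grey) and each array labelled knockout (orange), with circles, squares and triangles for replicates 1, 2 and 3 and black bars for the mean ± SD of n = 3. Stab2 (8.11 against 6.82) and Lyve1 (9.60 against 8.46) lie lower and Gata4 (9.91 against 10.42) and Cav1 (6.97 against 8.39) higher in livers labelled knockout, and Ttn stands out in control replicate 2 (7.08).

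Matrix and mesenchymal genes were higher. Of 16 basement membrane genes, 7 rose and 0 fell (15 higher adjusted over the list alone; median 0.47, and 0.38 against control replicate 2 alone), among them the laminin chains Lama4 (1.13, SE 0.13, adjusted p = 0.00979), Lamb1 (0.90) and Lamb2 (0.57) and the collagen gene Col15a1 (1.01). Of 25 fibrillar and interstitial matrix genes, 8 rose and 1 fell (17 and 1 adjusted over the list alone; median 0.43, and 0.40 against control replicate 2 alone). The proteoglycan Vcan (1.19), fibulin Fbln1 (0.86) and the collagen cross-linking enzymes Loxl2 (0.74) and Lox (0.71) rose, Thbs1 fell by 0.82, and Col1a1 did not pass (0.56, adjusted p = 0.1). In the list of stellate cells, the perisinusoidal mesenchyme of the liver, 6 of 23 rose and 0 fell (14 and 1 adjusted over the list alone; median 0.47, and 0.53 against control replicate 2 alone), among them Rgs5, Hand2 (0.71), the PDGF receptor Pdgfrb (0.56) and vimentin Vim (0.42). Camera gave these 3 lists adjusted p-values of 1.50e-13, 7.44e-11 and 2.35e-09, and each had an adjusted p = 0.166 with an estimated correlation. Their medians of 0.43 to 0.47 compare with 0.35 for hepatoblast, 0.33 for mesothelial, 0.30 for shared endothelial and 0.03 for hepatocyte metabolism genes. Whether matrix and mesenchymal genes rose beyond other non-blood genes was not tested.

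Mesothelial markers rose in 2 of 12 cases, Bnc1 (0.79) and Krt19 (0.52), while Aldh1a2 (0.88, adjusted p = 0.174) and Msln (−0.23, adjusted p = 0.179) did not pass (2 higher adjusted over the list alone; list median 0.33, and 0.14 against control replicate 2 alone; adjusted p = 0.0105). The mesothelial list call was lost without labelled knockout replicate 3 (median 0.15, adjusted p = 0.14), with a sex term (0.0735), with an estimated correlation (adjusted p = 0.272) and by fry (0.104).

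Hepatoblast genes shifted slightly upward. Of 32 measured, 2 rose, the pioneer factor Foxa1 (0.75, SE 0.14, adjusted p = 0.0266) and Tbx3 (0.73, SE 0.11, adjusted p = 0.0142), and 30 did not pass, among them Krt18 (0.50, adjusted p = 0.0756) and Serpinc1 (0.49, adjusted p = 0.0962). The median was 0.35, and 0.35 against control replicate 2 alone, and the count adjusted over the list alone was also 2. The list's adjusted p was 3.11e-05 by camera, 0.104 by fry, and adjusted p = 0.285 with an estimated correlation. Per array the list read 0.39, 0.05 and 0.46 in labelled knockout replicates 1, 2 and 3. Albumin Alb (−0.05, adjusted p = 0.847) and alpha-fetoprotein Afp (0.07, adjusted p = 0.743) did not pass, and both read above 13.3, near the top of the scale. No gene of 23 in hepatocyte metabolism passed (also 0 adjusted over the list alone; median 0.03, and 0.10 against control replicate 2 alone; list adjusted p = 0.259, and 0.0266 with a sex term). The smallest p there was that of glycogen synthase Gys2 (0.60, adjusted p = 0.0584), followed by Hpd (0.54, adjusted p = 0.0660), Scd1 (0.68, adjusted p = 0.145) and Tat (0.29, adjusted p = 0.151). Among 16 genes of iron homeostasis the iron exporter Slc40a1, abundant in macrophages, fell by 1.14 (SE 0.13, adjusted p = 0.00932), and the list did not pass (median −0.04, and −0.09 against control replicate 2 alone; adjusted p = 0.393). Smad6 (0.54), Atoh8 (0.45) and Bmp6 (−0.37) of that list did not pass. Adjusted over the list alone, 3 iron genes were higher and 4 lower, these 3 among them.

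Erythroid genes were lower throughout. All 31 measured had a negative log2 fold change, 16 fell past the threshold and 27 did so adjusted over the list alone, with a median of −0.81 and −0.79 against control replicate 2 alone. The erythroid transcription factors Tal1 (−0.98, SE 0.10, adjusted p = 0.0074), Nfe2 (−0.89, SE 0.11, adjusted p = 0.0106) and Klf1 (−0.80, SE 0.15, adjusted p = 0.0256), the erythropoietin receptor Epor (−0.83, SE 0.10, adjusted p = 0.0107) and the blood group protein Xk (−0.68, SE 0.11, adjusted p = 0.0204) fell. Of 9 heme synthesis genes, 3 fell, Uros (−1.07), Urod (−0.71) and Alad (−0.70), and 8 did so adjusted over the list alone (median −0.70, and −0.62 against control replicate 2 alone); Slc25a38 did not pass (−0.57, adjusted p = 0.0578). The embryonic globins, made by primitive red cells of the yolk sac, did not pass: Hbb-y differed by −0.06, Hba-x by −0.03 and Hbb-bh1 by 0.02 (adjusted p = 0.778, 0.939 and 0.967, and 0 passed adjusted over the list alone). Hbb-y read 13.66 in control livers, near the top of the scale, while Hba-x and Hbb-bh1 read 11.61 and 11.95. Globin paralogs share sequence, so a feature may read more than its own gene. Adjusted p-values were 1.38e-22 for the erythroid and 1.57e-06 for the heme list by camera, and adjusted p = 0.175 and 0.217 with an estimated correlation. The Klf1 call was lost without labelled knockout replicate 2 (adjusted p = 0.0506), labelled knockout replicate 3 (0.0847), control replicate 2 (0.0741) or control replicate 3 (0.0982).

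Macrophage and granulocyte genes were lower as well. Of 22 macrophage genes, 13 fell and 0 rose (17 lower and 2 higher adjusted over the list alone; median −0.77, and −0.63 against control replicate 2 alone). Besides Spic, the phosphatidylserine receptor Timd4 (−1.48, SE 0.16, adjusted p = 0.00827), the scavenger receptor Marco (−1.12, SE 0.12, adjusted p = 0.00813) and the chemokine receptor Cx3cr1 (−0.77, SE 0.09, adjusted p = 0.00932) fell. Of 20 granulocyte and myeloid genes, 12 fell and 0 rose (18 lower adjusted over the list alone; median −0.84, −0.70 against control replicate 2 alone, and −1.30 with the dimmest 50% of genes left out), including Cpa3, Ms4a3, the calcium-binding protein S100a9 (−1.20, SE 0.20, adjusted p = 0.0187) and the neutrophil protease Ctsg (−0.67, SE 0.12, adjusted p = 0.0230). Camera gave adjusted p-values of 2.15e-19 and 4.05e-14, and both lists had an adjusted p = 0.166 with an estimated correlation.

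Of 17 megakaryocyte genes, 6 fell and 16 did so adjusted over the list alone (median −0.82, and −0.74 against control replicate 2 alone). They included the platelet receptors Gp6 (−1.18, SE 0.26, adjusted p = 0.0401), Gp5 (−0.87, SE 0.19, adjusted p = 0.0366) and Treml1 (−1.06, SE 0.18, adjusted p = 0.0197), and Thbs1. Of 21 stem and progenitor genes, 3 fell and 18 did not pass (11 lower and 2 higher adjusted over the list alone; median −0.33, and −0.33 against control replicate 2 alone). These were Ptprc, the pan-leukocyte antigen CD45 (−1.16, SE 0.17, adjusted p = 0.0146), Lmo2 (−0.61, SE 0.14, adjusted p = 0.0439) and Cd48 (−0.50, SE 0.10, adjusted p = 0.0314), while Slamf1 (−1.29, adjusted p = 0.0568) and the stem cell factor receptor Kit (−0.36, adjusted p = 0.152) did not pass. Adjusted p-values were 5.90e-10 for the megakaryocyte list and 0.00168 for the progenitor list by camera, adjusted p = 0.226 and 0.173 with an estimated correlation, and 0.0544 and 0.0240 by fry. Lymphoid genes did not pass as a list (12 measured, 1 higher adjusted over the list alone, median −0.11, and −0.02 against control replicate 2 alone; adjusted p = 0.503). Ebf1 rose (0.49, adjusted p = 0.0447), and Cd3g (−0.29), Cd79b (−0.38) and Il7r (−0.15) did not pass.

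Hypoxia-response genes rose more than any other tested list by median. Of 21 measured, 15 rose, 0 fell and 6 did not pass (17 higher adjusted over the list alone, with a median of 0.86, and 0.87 against control replicate 2 alone). Outside the naming rule, Pgk1 (0.01, adjusted p = 0.985), Pdk1 (0.14, adjusted p = 0.502) and Ldha (0.23, adjusted p = 0.182) were among those that did not pass. The angiogenic factor Vegfa rose 2.45-fold (1.29, SE 0.09, adjusted p = 0.00525), and Ddit4, Bhlhe40 and the collagen prolyl hydroxylase P4ha2 (1.00, SE 0.12, adjusted p = 0.00944) rose as well. The list's adjusted p was 5.56e-28 by camera and adjusted p = 0.166 with an estimated correlation.

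**Figure D3:**
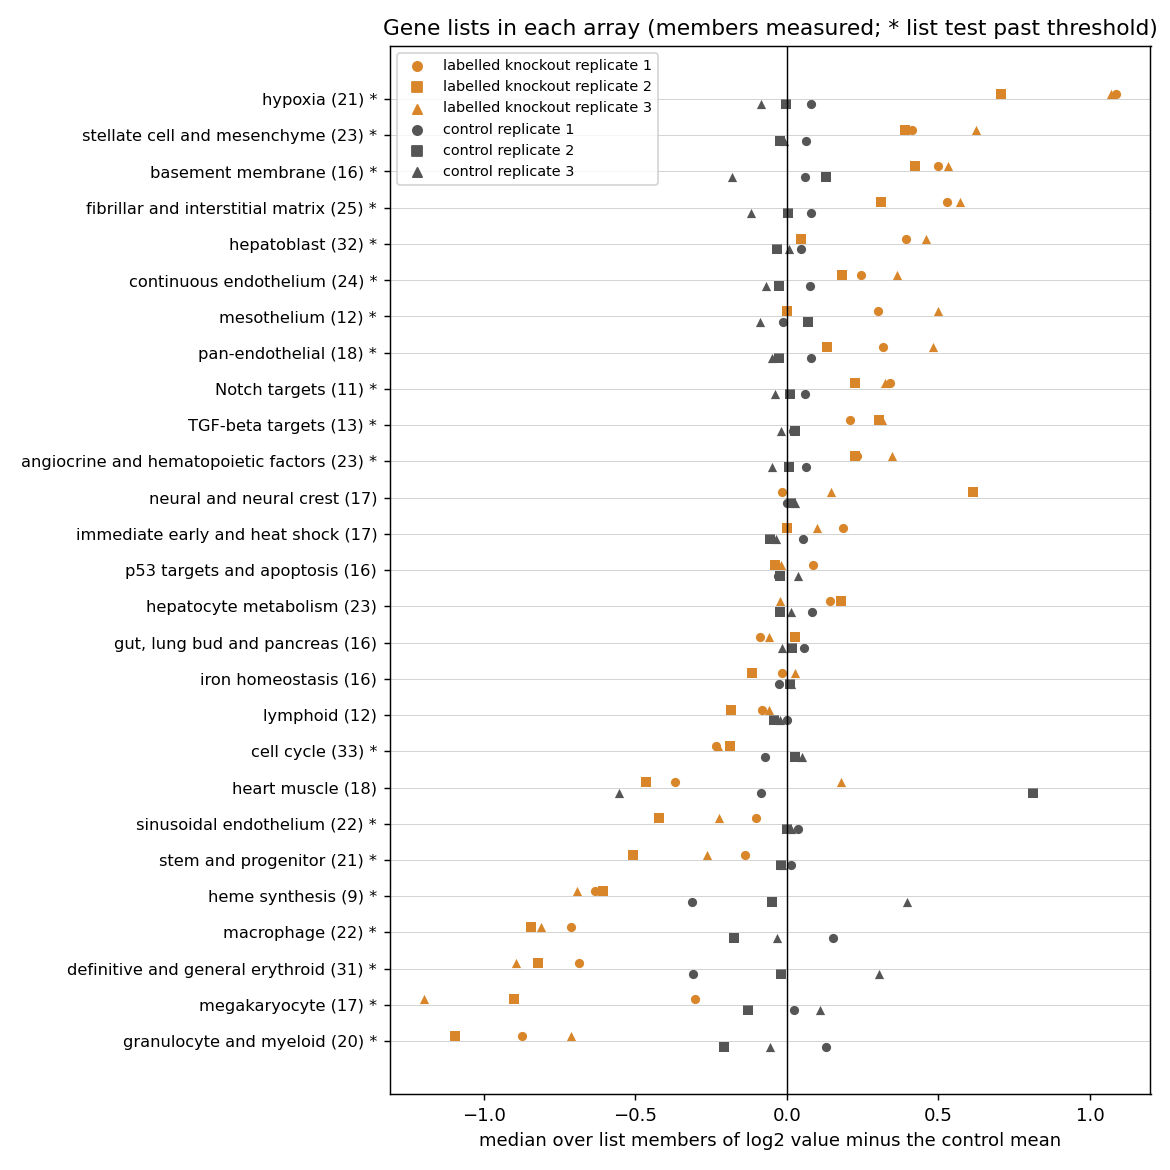
Per-array value of each of 27 gene lists (x axis: median over the members of the log2 value minus the control mean), with grey symbols for the 3 control arrays and orange symbols for the 3 arrays labelled knockout; numbers of members measured stand in brackets and a star marks an adjusted p under 0.05 by camera with the preset correlation. Hypoxia genes lie at 1.09, 0.71 and 1.07 and macrophage genes at −0.71, −0.85 and −0.81 in the arrays labelled knockout, and heart muscle genes at 0.81 in control replicate 2.

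Among angiocrine and blood-forming factors, signals that endothelium and mesenchyme send to other cells, 4 of 23 rose and 0 fell (7 higher adjusted over the list alone; median 0.24, 0.25 against control replicate 2 alone, and 0.42 with the dimmest 50% of genes left out). They were Tgfb2 (0.96), Rspo3, the Tie2 ligand Angpt2 (0.72) and Tgfb3 (0.52). Stem cell factor Kitl (0.61, SE 0.16, adjusted p = 0.0599) and Pdgfb (0.00, SE 0.12, adjusted p = 0.989) did not pass. Of 13 TGF-beta targets, Tgfbi rose (0.91, SE 0.16, adjusted p = 0.0253) and 12 did not pass, Skil (0.35), Itgav (0.33) and Smad7 (0.58) among them (5 higher adjusted over the list alone; median 0.26, and 0.20 against control replicate 2 alone). Of 11 Notch targets and ligands, the targets Hey1 (1.08, SE 0.15, adjusted p = 0.0126) and Hes1 (0.59, SE 0.10, adjusted p = 0.0187) rose, and Hey2 (0.59) and Dll4 (0.31) did not pass (2 higher adjusted over the list alone; median 0.26, and 0.25 against control replicate 2 alone). Camera gave these 3 lists adjusted p-values of 0.000289, 0.00392 and 0.000140, and each had an adjusted p = 0.166 with an estimated correlation. With a sex term the TGF-beta list call was lost (adjusted p = 0.0692).

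Cell cycle genes were slightly lower as a list. Of 33 measured, E2f1 fell (−0.47, SE 0.11, adjusted p = 0.0436) and 32 did not pass, Ccne1 (−0.42), Mcm5 (−0.48) and Cdc6 (−0.53) among them (4 lower adjusted over the list alone; median −0.21, and −0.24 against control replicate 2 alone; adjusted p = 2.20e-05 by camera and adjusted p = 0.245 with an estimated correlation). The E2f1 call was lost whichever array was left out (adjusted p from 0.0741 to 0.156). Myc did not pass (0.11, adjusted p = 0.709). The p53 and apoptosis list did not pass (16 measured, median 0.05, and 0.03 against control replicate 2 alone; adjusted p = 0.512). Of its members, Plk2 rose (0.77, adjusted p = 0.00932) and Ccng1 fell by 0.42 (adjusted p = 0.0312). Tnfrsf10b (0.54, adjusted p = 0.0544) and Cdkn1a (0.49, adjusted p = 0.0570) did not pass. Adjusted over the list alone, 4 were higher, these 2 among them, and 5 lower. Immediate early and heat shock genes, which respond to handling, did not pass as a list (17 measured, 1 higher adjusted over the list alone, median 0.13, and 0.03 against control replicate 2 alone; adjusted p = 0.297). Egr1 rose (0.93, SE 0.14, adjusted p = 0.0145), and Jun (0.73), Ier3 (0.80) and Junb (−0.32) did not pass.

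Markers of neighbouring tissues varied between single arrays. No heart muscle gene of 18 passed, also adjusted over the list alone, and the list's adjusted p was 0.307 (median −0.25). The median was 0.11 without control replicate 2. That array read 0.81 for this list against −0.09 and −0.55 in the other controls, and Ttn read 7.08 there against 4.83 and 4.36. Against control replicate 2 alone, which is also the difference that a sex term gives, the heart median was −0.95. By camera with the preset correlation the list passed without control replicate 3 (adjusted p = 0.00896) and without labelled knockout replicate 3 (0.0263). On all 6 arrays its adjusted p was 0.689 with an estimated correlation and 0.619 by fry. Other heart genes did not pass, among them Tbx5 (0.65), Nkx2-5 (−0.42) and Myh7 (−0.31). Neural genes read 0.61 in labelled knockout replicate 2 and −0.01 and 0.15 in replicates 1 and 3. The neural list did not pass (17 measured, 1 higher adjusted over the list alone, median 0.18, and 0.14 against control replicate 2 alone; adjusted p = 0.0757). Dcx rose (0.83, adjusted p = 0.0357), and Isl1 (1.44), Nefm (1.19) and Erbb3 (0.58) did not pass. The neural list passed without labelled knockout replicate 1 (adjusted p = 0.00107) or replicate 3 (0.0263). For gut, lung bud and pancreas genes no gene of 16 passed (also 0 adjusted over the list alone; median −0.01, and −0.01 against control replicate 2 alone; mean 0.10; adjusted p = 0.598). Barx1 stood at 1.29 (SE 0.61), Neurog3 at −0.32, Nkx2-1 at −0.27 and Cdx1 at −0.30.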

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

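The tests of embryo sex were written down before their results were seen. The count over other splits and the tests of equal blood loss, of blood cell share, of handling and of swapped arrays were chosen after the results were seen, and the bounds for equal loss and for blood cell share were set, as 95% intervals with 4 degrees of freedom, when their values were already known. Except in the globin test, they replaced a bound of 2 standard errors, under which equal loss of definitive blood cells, and blood cell share for Gata4, would have been argued against and not left open. The bound for embryo sex, 2 standard errors against control replicate 2, was wrong by design, because only that 1 control lacks Y-linked signal and the standard error is taken from the spread within both groups.

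Of 1198 features with no gene name here, which no comparison above used, 63 passed the gene test, 40 higher and 23 lower in livers labelled knockout.

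For the count of 1480 genes, 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, gave as many, and the highest count of another split was 1. With 10 splits a share under 0.05 cannot be reached.

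The erythroid, megakaryocyte, macrophage and granulocyte lists were all lower in livers labelled knockout, with medians between −0.77 and −0.84. The embryonic globin features did not fall with these lists, but this cannot decide on an equal loss of all blood cell types, primitive red cells included. In the difference of group means of per-array list values the globins lay above the union of these 4 lists by 0.80 (SE 0.22, interval 0.19 to 1.40). That test rests on 3 genes, of which Hba-x differed by −0.03 and Hbb-bh1 by 0.02. It was chosen with these values already seen, and the union leaves out the progenitor and lymphoid lists, which fell less (medians −0.33 and −0.11). Hbb-y read near the top of the scale, and a globin feature may read paralogs. An equal loss of definitive blood cell types stays open, because in the same measure the erythroid list lay below the stem and progenitor list by a difference of −0.50 (SE 0.21) whose interval ran from −1.07 to 0.08. Embryo sex followed the groups in every array but control replicate 2, and it stays open. Over the 90 members of these lists the median was −0.78 (SE 0.14) against control replicate 2 and −0.82 in the main comparison. On the erythroid list that array read −0.02, between the −0.31 and 0.30 of the controls with Y-linked signal, but 1 array decides nothing. A fit with a sex term left these 4 lists lower (erythroid median −0.79), yet its group difference is for every gene the one to control replicate 2, so it adds no array. A lower share of blood cells and lower expression within them cannot be told apart in whole liver. The genotype that the labels name stays open as a candidate cause, as does a delay of liver development, for which no test was run.

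The hypoxia list was higher by a median of 0.86. A smaller share of blood cells as the whole cause stays open. The hypoxia list exceeded the stellate cell list, the non-blood cell type list that rose most, by 0.49 (SE 0.11, interval 0.19 to 0.79). The test was chosen after the hypoxia list was seen to have the highest median of all tested lists. An excess was thus built into the choice, and the interval does not allow for that. This excess is a difference of group means of per-array list values, not of the medians given above. Embryo sex stays open here too, since the median of 0.87 (SE 0.19) against control replicate 2 alone rests on that 1 array. Handling at dissection cannot be told apart from the groups, since members of the immediate early list go both ways and its median of 0.13 decides nothing. A response to scarcer red cells may be a candidate explanation and was not tested.

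Gata4 was higher by 0.51. A swap of 1 array between the groups is argued against, because 0 arrays correlated better on average with the other group than with their own. By single pairs, labelled knockout replicate 1 lay closer to control replicates 1 and 2 than to labelled knockout replicate 2. Each control, however, lay closer to both other controls than to any array labelled knockout, so no partner for a swap was out of place. A smaller share of blood cells stays open. Gata4 was set, in each array, against the median of the 67 hepatoblast, mesenchyme and mesothelium genes. The group means of this gap differed by 0.18 (SE 0.07), with an interval from −0.02 to 0.37. The median log2 fold change of those genes, a different measure, was 0.38. A feature that reads exons kept in the deleted allele could also hide a loss in endothelium, and no probe sequence was used here to test it.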

How the results depend on the processing

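The sex term was added after the data were seen; every other alternative was fixed beforehand. No result past the threshold in either fit changed sign (0 of 2571 gene and 0 of 511 list results, totals that include results passing in neither fit). For genes past the threshold in the main fit, leaving out 1 array or adding the sex term could not change the sign, because their groups did not overlap. The trend, robust eBayes, the replicate block and the other list tests leave the differences as they are. The lack of sign changes is therefore little evidence of stability. Among results that passed in neither fit, 18 gene and 5 list results changed sign, the lists being heart, iron, p53 and gut. Adding the trend, robust eBayes, renewed quantile normalisation, median centring, filters on dim genes, array weights or leaving out X and Y genes kept both counts within 1.5 times, the Gata4 call and the 9 primary list calls, as did averaging features; testing each feature alone, run for counts and genes but not for lists, kept the counts and Gata4; renewed normalisation moves little in data already quantile-normalised. Counts higher and lower were 405 and 281 with the replicate block, 3 and 0 with the sex term, 1430 and 1270 at an adjusted p of 0.1, and 532 and 394 with at least a 1.5-fold change. The 9 primary list calls held by camera with the replicate block, with the sex term and without any 1 array (highest adjusted p = 0.0119 without 1 array, progenitor). With the sex term the heart muscle list gained a call as well (median −0.95). That fit compares with control replicate 2 alone, the array in which heart genes stood out, so list calls in it can come from 1 array. Leaving out each array in turn gave 25 to 785 higher and 16 to 610 lower genes and a Gata4 difference of 0.41 to 0.60. Gata4 stayed at 0.51 (adjusted p = 0.0814) with the replicate block and was 0.46 (adjusted p = 0.310) with the sex term; over the alternatives its adjusted p ran from 0.0167 to 0.310. Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at −0.05, −0.01 and −0.08, and none correlated best with its own number. The sex term raised the median standard error of the 1480 genes from 0.121 to 0.173 while their median absolute difference went from 0.66 to 0.64; with 1 control of the matching sex, its 3 calls partly follow from its construction. With an estimated correlation the adjusted p was 0.166 for the sinusoidal, continuous endothelial, basement membrane, interstitial matrix and macrophage lists, 0.285 for hepatoblast, 0.175 for erythroid, 0.173 for progenitor and 0.226 for megakaryocyte genes, and 0 of the 19 list calls held. Fry gave 0.104 for hepatoblast and 0.0544 for megakaryocyte genes and called 15 of 27 lists. Of 86 named calls besides Gata4, 72 were lost without control replicate 3, 44 without labelled knockout replicate 3, 83 with the sex term and 24 with the replicate block, under which the neural list gained a call (0.0281). Where no construction is named, the cause was not tested. Dim features cannot be set against background here.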

Other observations

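The 6 lists and the gene cluster below were chosen after the data were seen, so their p-values describe these arrays and are not independent evidence; genes not named before lie outside the rule for named genes. Axon guidance receptors and ligands, many of which also steer vessels and mesenchyme, were higher: 11 of 30 rose and 0 fell (median 0.60, and 0.55 against control replicate 2 alone; camera adjusted p = 8.54e-16, and adjusted p = 0.0965 with an estimated correlation). The netrin receptors Unc5c (1.33, SE 0.13, adjusted p = 0.0074) and Dcc (1.11, SE 0.10, adjusted p = 0.0074) and the Slit receptor Robo1 (0.82, SE 0.10, adjusted p = 0.0095) were among them. Per array the list read 0.38, 0.65 and 0.58 in labelled knockout replicates 1, 2 and 3. Replicate 2, highest here, also stood apart on the neural list (0.61), and Slit2 (SD 1.07), Sema3c (0.91), Epha4 (0.58) and Nrp2 (0.52) varied between the arrays labelled knockout, each being highest in replicate 2. Genes of the amino acid response, switched on when amino acids are scarce, rose in 6 of 23 cases (median 0.33, and 0.40 against control replicate 2 alone; adjusted p = 3.07e-10, and adjusted p = 0.194 with an estimated correlation), with Slc7a3, Vldlr, Stc2, Adm2 (1.33), Cth (1.05) and the cystine transporter gene Slc7a11 (0.76). Slc7a3, Vldlr and Stc2 were already among the 10 largest rises under the naming rule. Asns (−0.06), Psat1 (0.03), Slc7a5 (0.11), Mthfd2 (0.12) and Atf4 (0.18) did not pass, nor did Chac1 (0.96) and Trib3 (0.82). Of 19 genes of brain-type endothelium, 4 rose (median 0.37, and 0.36 against control replicate 2 alone; adjusted p = 4.02e-09, and adjusted p = 0.0989 with an estimated correlation): Sparcl1, Prnd, the Wnt effector Lef1 (0.81) and the glucose transporter gene Slc2a1 (0.65), the last of these also a hypoxia-response gene. Glycolysis genes rose in 3 of 17 cases (median 0.28, and 0.30 against control replicate 2 alone; adjusted p = 4.32e-05, and adjusted p = 0.194 with an estimated correlation), and 6 of the 17 were in lists fixed beforehand.

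Phagocytosis and lysosome genes of myeloid cells, none of them in an earlier list, fell in 12 of 23 cases (median −0.80, and −0.64 against control replicate 2 alone; adjusted p = 1.70e-24, and adjusted p = 0.0989 with an estimated correlation), among them cathepsin Ctss (−1.24), the tetraspanin Cd53 (−1.45) and the fungal receptor Clec7a (−1.52). Interferon-response genes fell in 3 of 21 cases, Ifi47 (−1.19), Igtp (−0.92) and Psmb8 (−0.63) (median −0.21, and −0.24 against control replicate 2 alone; adjusted p = 0.000776, and adjusted p = 0.251 with an estimated correlation).

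A run of 40 neighbouring genes that holds the imprinted cluster of Dlk1, Meg3 and Rian had more rises than any such run on another chromosome: 14 rose, 0 fell and 36 of 40 had a positive log2 fold change (median 0.67). The highest number elsewhere was 8. The noncoding RNAs Meg3 (0.86, SE 0.12, adjusted p = 0.0126) and Rian (0.68, SE 0.11, adjusted p = 0.0167) rose, and so did 11 of the 32 microRNA and small nucleolar RNA features, such as Mir329 (1.23, SE 0.19, adjusted p = 0.0161). Many of these small RNAs lie within longer transcripts of the cluster, so their features are not independent. Dlk1 did not pass (0.35, adjusted p = 0.165). Among 40 neighbours of Gata4, 3 passed, all higher: Fdft1 (0.50), Sox7 (0.75) and Fzd3 (0.81). Of all genes tested 6.36% passed, so this number is close to the general share.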
